A study of Mus musculus with 6 samples.

How the data were processed

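RNA was measured in mouse lens capsules that carried the lens epithelial cells left behind after removal of the fiber cell mass, a mouse model of cataract surgery. There were 6 libraries, 3 from capsules taken at 0 h and 3 from capsules taken 72 h after surgery. Per the series design, each library pooled 5 capsules of one interval, and both eyes of a mouse were operated on 72 h apart, so that the 2 intervals could come from the eyes of the same animals. The sources do not say which capsules were pooled with which beyond calling the 3 libraries of an interval biological replicates, so the p-values measure the spread between these pools. The labels give the strain as C57BL/6 and the genotype as wildtype. The sample descriptions of all 6 libraries also carry the tag RUNX_Cre_N, whose meaning is not given in the sources used here, so what it says of the genotype, and of Runx1 in particular, is open.

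Total RNA was extracted with the Qiagen RNeasy Mini Kit and libraries were made with the Takara SMARTer Stranded Pico v2 kit, per the labels' protocols. The deposited files hold raw read counts per Ensembl gene, one file per library, which are whole numbers with no normalization by the authors. HISAT2, HTSeq, edgeR and the mouse genome build GRCm39 are named in the submitters' processing notes. The versions, the annotation release and the strand setting used in counting were not given in the sources used here. Counts of antisense and overlapping genes are therefore uncertain, and so are those of near-identical paralogs such as the gamma crystallins, the hemoglobins and the histocompatibility genes, between which counting could split or drop reads.

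Each file lists 56940 genes and 5 further lines of reads assigned to no gene. Those lines held 44.0% ± 1.82 of all counted reads at 0 h and 49.7% ± 1.86 at 72 h (SD, n = 3), and were left out of library sizes and tests. Counts in genes ranged from 11338820 to 12432688 at 0 h and from 8453450 to 8945397 at 72 h. Symbols were taken from a GENCODE annotation of another mouse build by Ensembl identifier, which matched 51947 of the 56940 identifiers. No coordinates are given, because that build differs from the build of the files.

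Genes with enough counts were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total count of 15, which left 15407 genes. Composition was normalised by TMM, and time was tested with edgeR's quasi-likelihood test with robust dispersions (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The model held the time after surgery and no other term. Log2 fold changes are 72 h over 0 h with a prior count of 0.125, and their standard errors were derived from the fold change and the F statistic. Levels are CPM, the counts scaled by edgeR to the TMM-adjusted library size, as mean ± SD over 3 libraries.

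Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the pooled group. Where it had 1 to 3 counts, the ratio of the pooled counts is given with an exact 95% interval. PCR copies are not independent molecules, so these intervals and bounds cover counting error only. Shares of counts were compared by an exact two-sided permutation test of the difference of means, which cannot give a p under 0.1 with 3 libraries against 3.

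A set of 22 gene lists and 13 lists of cell type markers was fixed before the data were examined, with the tests and the alternatives. The lists hold 518 genes, of which 517 were found in the files and 442 were tested. Lists with 3 or more tested members (32 of 35) were tested with camera in its count version (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera asks whether a list moved against all other genes. It was repeated with the correlation estimated from the residuals, a version that also takes the few residual degrees of freedom of 6 libraries. Fry, which asks whether the genes of a list moved on balance one way and does not compare them with other genes, was run beside it. For each list, members that passed the per-gene test were counted with p-values adjusted over all tested genes and again adjusted over the list alone.

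Genes are named in the text by a rule fixed with the lists. It takes Runx1 (ENSMUSG00000022952), Pax6 (ENSMUSG00000027168), Foxe3 (ENSMUSG00000044518), Acta2 (ENSMUSG00000035783), Fn1 (ENSMUSG00000026193), Tgfb2 (ENSMUSG00000039239), Itgb8 (ENSMUSG00000025321) and Spp1 (ENSMUSG00000029304) whatever their result. It adds the 5 largest rises and the 5 largest falls by fitted log2 fold change among called genes with a mean of at least 10 CPM and an approved symbol. From each list it adds the 2 called members with the smallest p, or the one with the smallest p in each direction where members were called in both. The rule allows a member to be left out where a list has fewer than 3 tested genes. It gave 78 genes, not all of which are named here, and other genes are said to have been chosen after their values were seen.

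Alternatives were the sample number as a replicate block, DESeq2 size factors, upper quartile normalization, library size alone, no filter and a stricter filter at a mean of 50 counts, removal of crystallin, mitochondrial and hemoglobin genes, the DESeq2 1.42.0 Wald test, limma voom, a threshold of 0.01, and each library left out in turn. Separately, list counts were set beside those without 1 doubted library of each group, a choice made after seeing the data. The steps were tested on simulated data for this comparison, with 14924 genes of which 200 were changed. The share of changed genes recovered was 14% at 1.5-fold, 44% at 2-fold, 80% at 4-fold and 94% at 8-fold, and 3 of 119 calls fell on unchanged genes. Of 200 simulated lists of unchanged genes, 3 had a camera p under 0.05. Genes were simulated independently of each other, so this does not test camera on lists whose members are correlated. The estimated correlation of the real photoreceptor list was 0.87.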

Results

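Gene expression was measured by RNA sequencing in mouse lens capsules with their attached epithelial cells, taken at 0 h or 72 h after the fiber cell mass was removed. Each group held 3 libraries of 5 pooled capsules. The number of genes with at least 1 count ranged from 21664 to 22139 at 0 h and from 19750 to 20287 at 72 h. The first principal component of log2 CPM carried 70.7% of the variance and separated the groups. The second carried 14.8% and set 72 h replicate 3 apart from the other two 72 h libraries. Correlations of log2 CPM across genes, which are not independent replicates, were 0.971 to 0.973 between 0 h libraries and 0.897 to 0.941 between 72 h libraries. Counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 7.44.

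The makeup of the libraries shifted between 0 h and 72 h. Crystallin genes, which encode the main soluble proteins of the lens, held 16.2% ± 0.552 of the counts at 0 h and 1.96% ± 0.800 at 72 h (SD, n = 3; exact permutation p = 0.1, the smallest possible). RNAs encoded in the mitochondrial genome held 3.85% ± 0.0862 at 0 h and 20.01% ± 4.67 at 72 h (SD, n = 3; exact permutation p = 0.1, the smallest possible). Most of the latter share was mitochondrial ribosomal RNA, at 3.25% ± 0.0669 and 17.9% ± 4.24. Retinal photoreceptor markers held 0.124% ± 0.0626 at 0 h and 0.0115% ± 0.00578 at 72 h. Keratin genes held 0.589% in 72 h replicate 3, against 0.00476% and 0.0179% in the other two 72 h libraries and 0.0112% ± 0.00222 at 0 h.

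**Figure D1:**
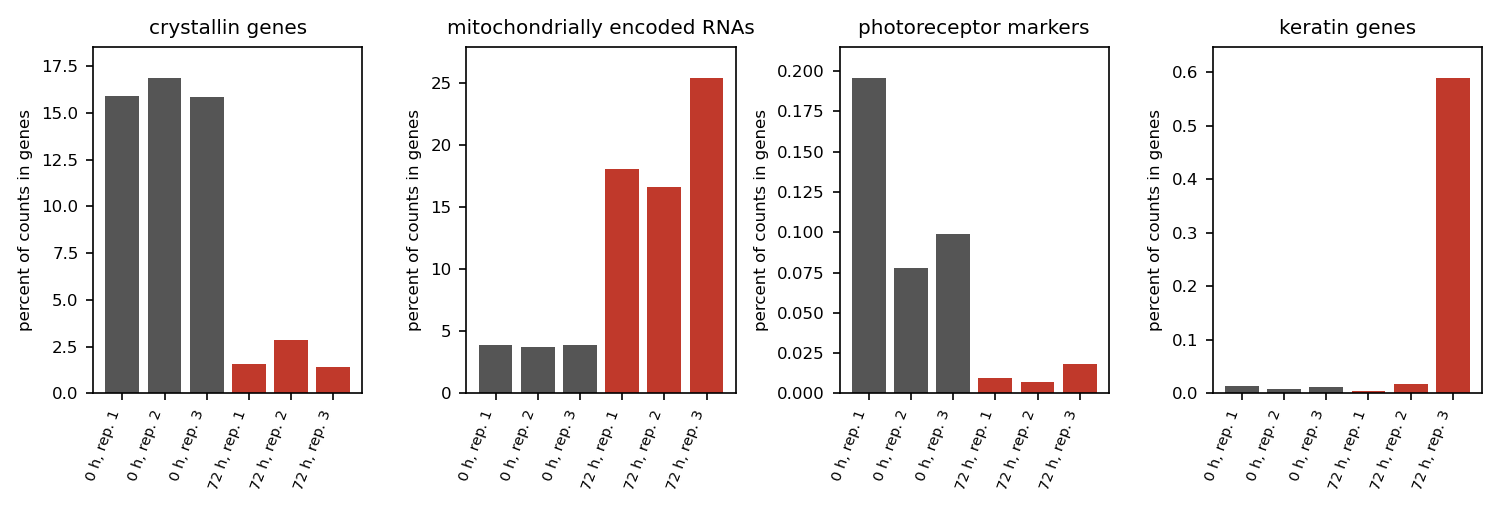
Percent of counts in genes (vertical axes, one bar per library, grey for 0 h and red for 72 h) held by crystallin genes, mitochondrially encoded RNAs, photoreceptor markers and keratin genes. Crystallins averaged 16.2% at 0 h and 1.96% at 72 h, and the keratin share of 0.589% stood out in 72 h replicate 3.

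The study's comparison asked which transcripts of the capsule changed by 72 h after surgery. Runx1, a transcription factor with roles in blood and epithelial cells, rose from 2.98 ± 1.02 to 382 ± 19.6 CPM (SD, n = 3 each), a log2 change of 6.99 ± 0.23 (SE). Fibronectin (Fn1), a matrix glycoprotein of wounds, rose from 17.3 ± 3.74 to 3172 ± 399 CPM, a log2 change of 7.52 ± 0.20. Smooth muscle actin (Acta2), a myofibroblast marker, rose from 113 ± 26.3 to 653 ± 54.5 CPM, a log2 change of 2.53 ± 0.17. Osteopontin (Spp1), a secreted phosphoprotein of matrix and of immune cells, rose from 0.535 ± 0.291 to 654 ± 335 CPM. Foxe3, a transcription factor of lens epithelium, fell from 249 ± 8.85 to 58.4 ± 4.92 CPM.

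Across the 15407 tested genes, 3230 rose and 2700 fell at 72 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 9477 were not called. Changes of at least 2-fold were called for 2086 higher and 1610 lower genes. The values of the groups did not overlap for 8238 genes (53.5% of those tested, where chance gives 10%). Without 72 h replicate 3 the counts were 3646 higher and 3265 lower, and without 0 h replicate 1 they were 2518 and 1921.

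Of the 8 genes fixed in advance, 7 passed the test. Adjusted p was 8.1e-08 for Runx1, 1.6e-08 for Fn1, 4.9e-06 for Acta2, 6.4e-07 for Foxe3 and 5.5e-04 for Spp1, whose log2 changes were 10.24 ± 0.79 for Spp1 and −2.09 ± 0.11 for Foxe3. Transforming growth factor beta 2 (Tgfb2) rose by 1.12 ± 0.11 on the log2 scale (adjusted p = 3.6e-05). Integrin beta 8 (Itgb8), a subunit of a receptor that activates latent TGF-beta, rose by 0.82 ± 0.16 (adjusted p = 0.0028). Pax6, a transcription factor needed for eye formation, was at 684 ± 23.0 CPM at 0 h and 643 ± 91.5 CPM at 72 h and was not called (log2 change −0.09 ± 0.11, adjusted p = 0.575). Every library of one group lay beyond every library of the other for all 77 called genes among the 78 that the naming rule gave. Apart from the fixed genes, these were chosen by small p or large change in the same libraries, so this adds no separate support.

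By fitted log2 change, which rests on the prior count where a group has 0 counts, the 5 largest rises among well-measured genes were those of Lgr6, Plaur, Igfbp3, Adamts14 and Tnc. The bounds of Lgr6, Plaur and Adamts14, which had 0 counts at 0 h, do not place them above Spp1. Lgr6, an R-spondin receptor, had 0 counts at 0 h and 52.8 ± 20.6 CPM at 72 h, at least 639-fold higher. Plaur, the urokinase receptor, was at least 569-fold higher, and the procollagen peptidase gene Adamts14 at least 455-fold higher, both from 0 counts at 0 h. Igfbp3, an insulin-like growth factor binding protein, had 2 counts at 0 h and 5691 at 72 h, a ratio of 4027 (95% counting interval 1114 to 33264). Both 0 h counts lay in 0 h replicate 2, without which the rise was at least 1805-fold from 0 counts. Tenascin C (Tnc), a matrix protein of wounds, rose by 10.93 ± 0.58 on the log2 scale (11.77 without 0 h replicate 3). By the same measure the 5 largest falls were those of Crygd, Rgs4, Crygb, Crygc and Emilin3. Rgs4, a regulator of G protein signalling, had 1307 counts at 0 h and 2 at 72 h, 462-fold lower (95% counting interval 128 to 3817). Both 72 h counts lay in 72 h replicate 1, without which the fall was at least 203-fold to 0 counts. Emilin3, which encodes an extracellular glycoprotein, fell by 7.34 ± 0.50 on the log2 scale (log2 change −8.43 without 72 h replicate 2).

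**Figure D2:**
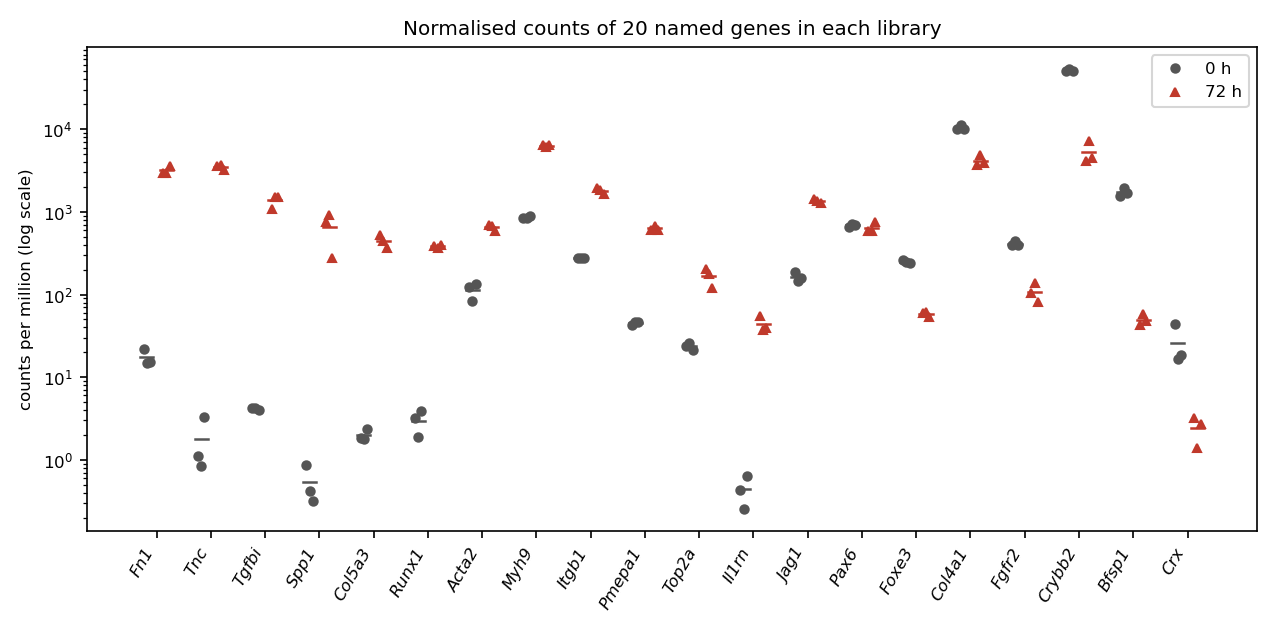
CPM on a log scale (vertical axis) of 20 named genes (horizontal axis) in each 0 h library (grey circles) and 72 h library (red triangles), with the group means as lines. Fn1 went from a mean of 17.3 to 3172 CPM, Bfsp1 from 1722 to 49.3 CPM, and the groups overlapped for Pax6.

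Genes of the differentiated lens fell as a group. Among crystallins, 14 of 15 tested members fell and none rose, and adjusted over the list alone all 15 fell. Crybb2 fell from 51689 ± 1658 to 5276 ± 1711 CPM (log2 change −3.29 ± 0.21), and Crybb3 by 1.90 ± 0.18 on the log2 scale. The gamma crystallins Crygd (−8.71 ± 1.11), Crygb (−7.89 ± 0.80) and Crygc (−7.69 ± 0.69) fell too, although reads of these near-identical paralogs are uncertain and their 0 h levels varied widely, as for Crygd at 87.5 ± 68.6 CPM. The change was −7.86 without 0 h replicate 2 and −10.29 without 72 h replicate 3 for Crygd, and −8.38 without 72 h replicate 1 for Crygc. The call of Crygd was lost with limma voom (adjusted p = 0.0805; 8.1e-13 to 0.0805 over all alternatives). The camera test placed the crystallins below other genes (adjusted p = 4.4e-14), and adjusted p = 0.143 with an estimated correlation.

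Of 17 tested lens fiber cell genes other than crystallins, 16 fell both over all genes and adjusted over the list alone, and none rose. Bfsp1, which encodes the beaded filament protein filensin, fell from 1722 ± 204 to 49.3 ± 7.48 CPM (−5.13 ± 0.16), and Tdrd7, a component of RNA granules needed for lens clarity, fell by 2.67 ± 0.13. The list lay below other genes (camera adjusted p = 6.3e-18; adjusted p = 0.109 with an estimated correlation). Lens epithelial identity genes fell for 12 of 15 members, none rose, and the count was the same adjusted over the list alone. Beside Foxe3, Mab21l1, a gene required for lens formation, fell by 1.57 ± 0.16. The list median was −1.10 (camera adjusted p = 5.9e-06; adjusted p = 0.0857 with an estimated correlation). In the same libraries the photoreceptor share was 0.124% of counts at 0 h and 0.0115% at 72 h. Higher at 72 h were 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers. Here and below these are shares of the tested markers, from fixed lists of 16, 12 and 10. A marker with 0 counts at 0 h passed the filter only through its 72 h counts and could only rise. This held for 4 of the 6 neutrophil markers.

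Genes of the lens capsule and basement membrane moved both ways, with 4 of 17 higher and 8 lower, and the same counts adjusted over the list alone. Col4a1, a chain of the main capsule collagen, fell from 10441 ± 719 to 4171 ± 605 CPM (−1.32 ± 0.12), while the proteoglycan gene Agrn rose by 1.84 ± 0.12. The list as a whole was not called (camera adjusted p = 0.426). Without 0 h replicate 1, 2 or 3, 5 members fell in each case.

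Cytoskeletal genes of contraction rose together. All 18 tested members of the contractile list rose over all genes and adjusted over the list alone, with a median log2 change of 2.44. Tpm4, a tropomyosin, rose from 86.8 ± 5.38 to 755 ± 43.2 CPM (3.12 ± 0.10), and Myh9, the heavy chain of nonmuscle myosin IIA, from 859 ± 31.3 to 6334 ± 170 CPM (2.88 ± 0.10). This list was called by camera (adjusted p = 3.2e-32), and it alone kept its call with an estimated correlation (adjusted p = 0.025). The other 20 called lists lost theirs. In the same libraries 12 of 15 macrophage and monocyte markers and 5 of 6 neutrophil markers were higher too.

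Fibrillar and wound matrix genes rose for 17 of 23 members and fell for 1, and adjusted over the list alone 18 rose and 1 fell. Tgfbi, a secreted matrix protein induced by TGF-beta, rose from 4.16 ± 0.123 to 1381 ± 250 CPM (8.37 ± 0.19), whereas Col6a2, a chain of collagen VI, fell by 1.37 ± 0.17. The median log2 change was 4.14 (camera adjusted p = 5.2e-26; adjusted p = 0.0857 with an estimated correlation). Matrix proteases and their inhibitors rose for 10 of 14 members and fell for 2, and adjusted over the list alone for 11 and 3. Tissue plasminogen activator (Plat) rose by 3.19 ± 0.18, and the metalloproteinase inhibitor Timp2 fell by 0.66 ± 0.12 (camera adjusted p = 3.0e-09; adjusted p = 0.13 with an estimated correlation). Integrin genes, which encode matrix receptors, rose for 10 of 13 members and fell for 2 by either adjustment, over all genes or adjusted over the list alone. Itgb1 rose from 276 ± 2.10 to 1807 ± 136 CPM (2.71 ± 0.10), and the laminin receptor subunit Itga6 fell by 1.11 ± 0.09 (camera adjusted p = 1.8e-05; adjusted p = 0.0857 with an estimated correlation).

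In the TGF-beta pathway and its target genes, 14 of 22 members rose and 3 fell, and adjusted over the list alone 16 rose and 3 fell. Pmepa1, a feedback inhibitor induced by TGF-beta, rose by 3.80 ± 0.11, and Id1, a target of bone morphogenetic protein signalling, fell by 1.49 ± 0.26 (camera adjusted p = 5.6e-08; adjusted p = 0.154 with an estimated correlation). Of 11 tested mesenchymal transition regulators and markers, 6 rose and none fell, and adjusted over the list alone 6 rose and 1 fell. Over all genes 1 member fell with the replicate block, upper quartile normalization, no filter, the stricter filter, DESeq2 or limma voom, and without 72 h replicate 2. Beside Runx1, the transcription factor gene Sox9 rose by 1.08 ± 0.10 (camera adjusted p = 6.7e-05; adjusted p = 0.0857 with an estimated correlation). In the libraries in which these matrix, protease, integrin, TGF-beta and mesenchymal genes were higher, markers of macrophages and neutrophils were higher too, with 12 of 15 and 5 of 6 members called.

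**Figure D3:**
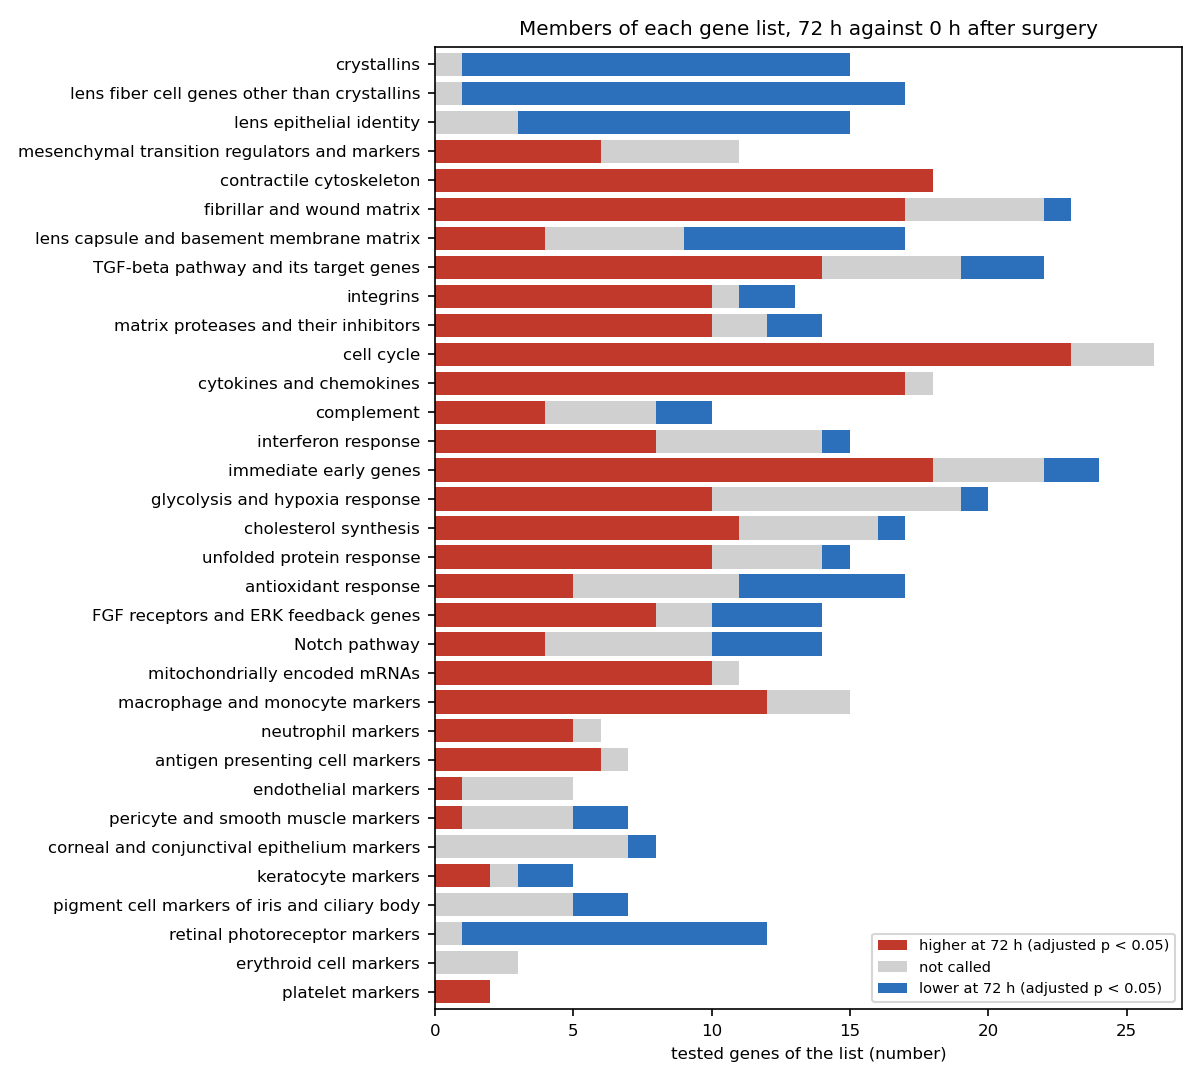
Number of tested genes (horizontal axis) of each fixed list that were called higher at 72 h (red), called lower (blue) or not called (grey) by the per-gene test over all genes. The bars show 18 of 18 contractile genes higher and 14 of 15 crystallins lower.

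Cell cycle genes rose for 23 of 26 members and fell for none, and adjusted over the list alone for 24. The DNA topoisomerase gene Top2a rose from 23.6 ± 2.27 to 167 ± 42.7 CPM (2.82 ± 0.19), and the transcription factor gene Foxm1, which drives mitotic genes, by 2.56 ± 0.23. The list was called (camera adjusted p = 2.1e-11; adjusted p = 0.213 with an estimated correlation). Immediate early genes, which many cells switch on within minutes of a stimulus, rose for 18 of 24 members and fell for 2 by either adjustment, over all genes or adjusted over the list alone. Socs3, a cytokine feedback inhibitor, rose by 4.13 ± 0.14, and the phosphatase gene Dusp1 fell by 1.11 ± 0.31 (camera adjusted p = 1.8e-14; adjusted p = 0.109 with an estimated correlation). The call of Dusp1 was lost without 0 h replicate 1 (adjusted p = 0.0694), 0 h replicate 2 (0.0584) or 72 h replicate 1 (0.0762; 1.1e-05 to 0.0762 over all alternatives). Without any one library other than 72 h replicate 3, 0 or 1 members of the list fell, and 1 with the replicate block or limma voom. In the libraries in which cell cycle and immediate early genes were higher, so were 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers.

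Among FGF receptors and ERK feedback genes, 8 of 14 rose and 4 fell, and adjusted over the list alone 8 rose and 5 fell. Spred1, an inhibitor of the ERK cascade, rose by 1.83 ± 0.11, and the receptor gene Fgfr2 fell from 412 ± 26.1 to 108 ± 28.1 CPM (−1.93 ± 0.17). The list was called higher (camera adjusted p = 0.019; adjusted p = 0.218 with an estimated correlation), and 2 members fell without any one of the 0 h libraries. Notch pathway genes rose for 4 of 14 members and fell for 4 by either adjustment, over all genes or adjusted over the list alone. The ligand gene Jag1 rose from 165 ± 20.7 to 1339 ± 72.2 CPM (3.02 ± 0.12), and Lfng, a glycosyltransferase that modifies Notch, fell by 1.52 ± 0.13. The list was not called (camera adjusted p = 0.576), and its median (−0.29; 0.03 under the stricter filter, and −0.19 to −0.08 without 0 h replicate 3 or any one 72 h library) and mean (0.30) differed in sign. In the same libraries 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers were higher too.

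Genes of the unfolded protein response rose for 10 of 15 members and fell for 1, and adjusted over the list alone for 11 and 1. The chaperone gene Calr rose by 1.42 ± 0.11 and Herpud1, which acts in protein degradation at the endoplasmic reticulum, fell by 1.07 ± 0.15 (camera adjusted p = 0.0022; adjusted p = 0.260 with an estimated correlation). Cholesterol synthesis genes rose for 11 of 17 members and fell for 1, and adjusted over the list alone for 12 and 1. Insig1, which restrains the pathway, fell by 1.31 ± 0.12 (camera adjusted p = 0.0030; adjusted p = 0.218 with an estimated correlation). With upper quartile normalization 2 members fell. In the same libraries 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers were higher too.

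Glycolysis and hypoxia response genes rose for 10 of 20 members and fell for 1, and adjusted over the list alone for 10 and 2. The lactate transporter gene Slc16a3 rose by 2.24 ± 0.19 and Ndrg1, a hypoxia-responsive gene, fell by 1.46 ± 0.13. The list was not called (camera adjusted p = 0.113), although it was without 72 h replicate 1 (adjusted p = 0.0243), without 72 h replicate 2 (adjusted p = 0.0310) or with no filter (adjusted p = 0.0215), in a range of 0.0215 to 0.490. The members that fell numbered 6 without 72 h replicate 3, 3 with upper quartile normalization, library size alone or no filter, and 2 with the replicate block or limma voom. Antioxidant response genes rose for 5 of 17 members and fell for 6 by either adjustment, over all genes or adjusted over the list alone. Glutathione reductase (Gsr) rose by 2.23 ± 0.15 and peroxiredoxin 6 (Prdx6) fell by 1.68 ± 0.12, and the list was not called (camera adjusted p = 0.630). Both lists were measured in libraries in which 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers were higher at 72 h.

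Mitochondrially encoded mRNAs rose for 10 of 11 tested members, and adjusted over the list alone for all 11. The gene mt-Nd1 rose from 790 ± 20.2 to 3074 ± 582 CPM (1.96 ± 0.13) and mt-Cytb by 1.83 ± 0.15 (camera adjusted p = 3.9e-08; adjusted p = 0.213 with an estimated correlation). The mitochondrial share of all counts was 25.3% in 72 h replicate 3, and 18.1% and 16.6% in the other two 72 h libraries. At 72 h 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers were higher too. The mitochondrial share had been chosen beforehand as a sign of RNA quality and library composition. Reads not aligned were also more frequent at 72 h (19.7% against 13.0% at 0 h). Whether the rise was technical was not tested.

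Inflammatory transcripts and immune cell markers were higher at 72 h. Cytokine and chemokine genes rose for 17 of 18 tested members by either adjustment, over all genes or adjusted over the list alone. Il1rn, an antagonist of interleukin 1, rose from 0.439 ± 0.189 to 43.9 ± 9.85 CPM (6.59 ± 0.34), and Ccl2, which attracts monocytes, by 3.32 ± 0.36 (camera adjusted p = 7.0e-12; adjusted p = 0.0857 with an estimated correlation). Macrophage and monocyte markers rose for 12 of 15 members, and adjusted over the list alone for 13. The integrin gene Itgam rose from 0.229 ± 0.217 to 45.3 ± 14.9 CPM (7.59 ± 0.56; 8.37 without 0 h replicate 1 and 6.99 without 0 h replicate 3), and the leukocyte antigen gene Ptprc by 3.35 ± 0.41 (camera adjusted p = 1.1e-05; adjusted p = 0.154 with an estimated correlation).

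Neutrophil markers rose for 5 of 6 tested members, and adjusted over the list alone for all 6. The fixed list held 12, and 4 of the 6 tested had 0 counts at 0 h, so these 4 could only rise. The tested member Ltf stood 5.12 log2 units above both other 72 h libraries in 72 h replicate 3. That library held the high keratin share, and without it 7 of 7 tested members rose. The receptor gene Csf3r rose by 4.41 ± 0.34, and Trem1 was at least 47.2-fold higher from 0 counts at 0 h. The list median was 7.81 from fitted values and 5.35 with the 4 members at 0 counts set to their bounds (camera adjusted p = 6.0e-04; adjusted p = 0.143 with an estimated correlation). Antigen presenting cell markers rose for 6 of 7 tested members, from a fixed list of 10, by either adjustment, over all genes or adjusted over the list alone. Itgax rose by 6.47 ± 0.64 (7.39 without 0 h replicate 1) and H2-Ab1, a class II histocompatibility gene whose reads near-identical relatives can share, by 2.02 ± 0.30 (camera adjusted p = 0.0018; adjusted p = 0.285 with an estimated correlation). None of the 12 T and NK cell markers or the 7 B cell markers had enough counts to pass the filter of the main test. With no filter 11 and 4 of them were tested and none was called, but a difference at such low counts could be missed at this depth. Of 6 platelet markers only 2 had enough counts for the main test, too few for a test of the list. Both rose over all genes and adjusted over the list alone, Pf4 by 4.42 ± 0.50 and Itga2b by 1.35 ± 0.42. The call of Itga2b was lost without any one library except 72 h replicate 3 (adjusted p 0.0595 to 0.0975; 0.0146 to 0.0975 over all alternatives). None of the 3 tested erythroid markers passed by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.426).

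Interferon response genes rose for 8 of 15 members and fell for 1, and adjusted over the list alone for 9 and 1. Gbp3, a guanylate binding protein gene, rose by 3.87 ± 0.65 (4.83 without 0 h replicate 2) and Ifit2 fell by 0.79 ± 0.22 (camera adjusted p = 0.034; adjusted p = 0.639 with an estimated correlation). The members that rose numbered 2 of 16 without 0 h replicate 1, 3 of 16 without 0 h replicate 2 or 0 h replicate 3, 5 of 15 with limma voom and 7 of 15 without 72 h replicate 3, but 11 of 16 without 72 h replicate 2, 11 of 18 with DESeq2 and 12 of 17 without 72 h replicate 1. The list lost its call under the stricter filter (adjusted p = 0.0898; 0.0011 to 0.0898 over settings), and that of Ifit2 was lost without 0 h replicate 1 (adjusted p = 0.0880) or 0 h replicate 2 (adjusted p = 0.0602; 0.0124 to 0.0880 over all alternatives). In the libraries in which interferon response genes were higher, so were 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers. Complement genes rose for 4 of 10 members and fell for 2, and adjusted over the list alone for 5 and 2. The receptor gene C3ar1 rose by 2.76 ± 0.58, and Cd59a, an inhibitor of the membrane attack complex, fell by 1.17 ± 0.36. The call of Cd59a was lost with no filter (adjusted p = 0.0577), without 72 h replicate 2 (adjusted p = 0.0572) or without any one 0 h library (adjusted p 0.0559 to 0.101; 0.0032 to 0.101 over all alternatives). The complement list was not called (camera adjusted p = 0.301), but without 72 h replicate 3, the library with the high keratin share, 7 members rose and it was (adjusted p = 0.0121; 0.0121 to 0.687 over settings). Without any other one library 1 to 3 members rose, and over all settings 0 to 2 fell.

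Markers of other eye tissues differed between groups or stood out in single libraries. Retinal photoreceptor markers fell for 11 of 12 members by either adjustment, over all genes or adjusted over the list alone. The transcription factor gene Crx fell from 26.2 ± 15.4 to 2.44 ± 0.953 CPM (−3.42 ± 0.48), and Rom1, an outer segment gene, by 2.06 ± 0.34 (camera adjusted p = 1.2e-05; adjusted p = 0.341 with an estimated correlation). The photoreceptor share was 0.195% in 0 h replicate 1 and 0.0778% and 0.0992% in the other two 0 h libraries. The number that fell was 9 without 0 h replicate 1, with the replicate block or with no filter, 8 without 72 h replicate 1, and 12 without 72 h replicate 3, with DESeq2 or with limma voom. Of 8 tested corneal and conjunctival epithelium markers, 1 fell and none rose by either adjustment, over all genes or adjusted over the list alone. Aldh3a1, an aldehyde dehydrogenase gene abundant in cornea, fell from 999 ± 192 to 248 ± 85.3 CPM (−2.01 ± 0.30). Krt5, a keratin of basal surface epithelium chosen after its values were seen, was at 1107 CPM in 72 h replicate 3 and 0.695 and 17.3 CPM in the other two 72 h libraries, and was not called. Aldh3a1 did not share this pattern, at 272 CPM in 72 h replicate 3 and 154 and 319 CPM in 72 h replicates 1 and 2. Its fall was therefore not shown to reflect corneal reads. The list median was 4.67, or 0.08 without 72 h replicate 3, 1.69 with the replicate block and 1.47 with limma voom, and its mean 3.41, while camera, which did not call it, put it below other genes (adjusted p = 0.913).

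Of 5 tested keratocyte markers, 2 rose and 2 fell by either adjustment, over all genes or adjusted over the list alone. Col5a3, a chain of collagen V, rose by 7.79 ± 0.20 and Aldh1a1, which makes retinoic acid, fell by 2.08 ± 0.30. The list was not called (camera adjusted p = 0.0743) except with no filter (adjusted p = 0.0249) or without 72 h replicate 1 (adjusted p = 0.0180; 0.0180 to 0.476 over settings), when 1 member fell. Pigment cell markers of iris and ciliary body fell for 2 of 7 members and rose for none, and adjusted over the list alone for 1. Oca2, a melanosome gene, fell by 4.57 ± 0.39 (log2 change −5.29 without 72 h replicate 1) and Pmel by 1.43 ± 0.51, a call that held only without 72 h replicate 1 among the fits that left out one library (adjusted p 0.0617 to 0.172 in the others). It was lost with limma voom too (adjusted p = 0.0545; 0.0338 to 0.172 over all alternatives). That list was not called (camera adjusted p = 0.137), except without 72 h replicate 1 (adjusted p = 0.0129; 0.0129 to 0.310 over settings). Among pericyte and smooth muscle markers, 1 of 7 rose and 2 fell by either adjustment, over all genes or adjusted over the list alone. The proteoglycan gene Cspg4 rose by 5.05 ± 0.49 and the receptor gene Pdgfrb fell by 1.00 ± 0.12 (camera adjusted p = 0.942), and 2 members rose without 72 h replicate 2 or with DESeq2. Of 5 endothelial markers, Erg rose by either adjustment, over all genes or adjusted over the list alone, from 1 count at 0 h to 71 at 72 h, a ratio of 100.5 (95% counting interval 17.5 to 4024). The 0 h count lay in 0 h replicate 2, without which the rise was at least 22.5-fold from 0 counts. Without 72 h replicate 3, 2 endothelial members rose, and without 72 h replicate 2 or with limma voom, 1 fell. The endothelial list was not called (camera adjusted p = 0.974), and its median (−0.48) and mean (0.71) differed in sign. The median lay above 0 without any one library (0.27 to 1.56) other than 72 h replicate 2 (−0.70).

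Over the 32 lists tested, camera called 21, of which 17 were higher and 4 lower at 72 h, and fry also called 21, with the keratocyte list (adjusted p = 0.0195) in place of the interferon list (adjusted p = 0.102). Time after surgery is the only difference between the groups that the labels give, and no label gives a batch, so a batch that followed the groups could not be tested. Library depth was lower at 72 h, and each p rests on 3 pools per group.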

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

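Reads that the deposited files assign to no gene, which the comparisons did not use, differed between the groups, with every 72 h library above every 0 h library in 3 classes and below every one in another. Reads that were not aligned made up 19.7% ± 4.07 of all counted reads at 72 h and 13.0% ± 1.28 at 0 h (SD, n = 3). Reads aligned to several places made up 7.32% ± 0.832 at 72 h and 4.53% ± 0.150 at 0 h, and reads of low alignment quality 3.84% ± 0.0974 and 3.29% ± 0.303. Reads in no annotated gene made up 17.7% ± 1.76 at 72 h and 22.0% ± 1.47 at 0 h. For each of the 4 classes the exact permutation p was 0.1, the smallest possible with 3 libraries against 3.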

How the results depend on the processing

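All alternatives were run except where a setting gave a list no test, and the counts of list members without 72 h replicate 3 or 0 h replicate 1 were added after seeing the data. The counts of genes stayed within 1.5 times of 3230 higher and 2700 lower genes under every alternative but one, a threshold of 0.01, which left 1671 lower genes by its own construction. With an estimated inter-gene correlation the number of lists called went from 21 to 1. Higher correlation between members cannot explain every lost call. The mesenchymal list lost its call at an estimated correlation of −0.035, below the preset 0.01 (camera adjusted p 6.7e-05 and then 0.0857). The integrin and epithelial identity lists lost theirs at 0.020 and 0.027. The 2 versions of camera also differ in degrees of freedom. With an estimated correlation camera takes the few residual ones of 6 libraries, and with a preset one those of all tested genes. For the same statistic the former gives a larger p, whatever the correlation. A lost call is therefore no measure of correlation between members. In the fits that left out one library, 2511 to 3646 genes were higher and 1877 to 3265 lower. In those fits 1838 to 2231 genes were at least 2-fold higher, 1236 to 1925 at least 2-fold lower, and 21 to 24 lists were called. The crystallin share differed by −14.7 to −13.9 percentage points and the mitochondrial share by 13.5 to 17.9. Among genes called in both, no gene had the opposite sign under any alternative that was compared gene by gene. Calls that were higher made up 54.5% in the main setting and 48.2% (upper quartile normalization) to 55.5% (DESeq2 size factors) under other scalings, none of which moved the median of all genes by more than 0.1.

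Deviations of libraries with the same replicate number in the labels correlated at −0.04, 0.06 and −0.01, so no pairing by number was detected. This does not show that equal numbers came from different mice. With the replicate block 2921 genes were higher and 2507 lower, 1950 and 1546 of them by at least 2-fold, 21 lists were called, and 5296 of the 5930 calls were shared. Not every library correlated best with the one of its own number.

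Of the 21 lists called, 20 kept their call in each of up to 13 settings that could test them, apart from the estimated correlation. The interferon list lost its call under the stricter filter (adjusted p = 0.0898; range over settings 0.0011 to 0.0898). Of 11 lists not called, 7 stayed so in all settings, and the complement, glycolysis, keratocyte and pigment cell lists were called in at least 1. Among 78 named genes, 22 values in 6 genes lost their call, 19 of them in fits without one library. The other 3 were Cd59a with no filter and Crygd and Pmel with limma voom.

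The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3230 higher and 2700 lower genes, 2086 and 1610 of them at least 2-fold, and 1 of the 10 splits gave as many. The highest of the other splits gave 0 genes by edgeR in each of these counts. Each other split mixed 0 h and 72 h libraries in both groups, which puts the change with time into the spread within groups. Few gene calls were therefore likely in advance, and these splits cannot gauge the real gene counts. At an unadjusted p under 0.05 the real split gave 7244 genes and the others 96 to 201, and no other tool was run on the splits. For lists, the real split gave 21 and the others 12 to 18, although they called 0 genes. Camera with its preset correlation thus called many lists in mixed groups too. Those groups still held unequal numbers of 72 h libraries, so they cannot gauge the real number of lists. That number alone says little about the grouping by time. With 200 of 14924 simulated genes changed, 14% of 1.5-fold changes and 44% of 2-fold changes were recovered, so smaller changes can be missed. The real comparison called 5930 of 15407 genes, so its adjusted threshold let larger p-values pass. The recovered shares therefore need not hold for it.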

Other observations

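The group in this paragraph was assembled after its values were seen, so its counts carry no test of direction. Among 31 growth factor genes, 15 rose and 8 fell, in libraries in which 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers were higher too. Pdgfb rose by 7.53 ± 0.25, Hbegf by 2.13 ± 0.12 and Fgf2 by 3.05 ± 0.24, and Areg, an epidermal growth factor receptor ligand, was at least 86.3-fold higher from 0 counts at 0 h. Fgf1 fell by 3.17 ± 0.63 and Bmp7 by 1.43 ± 0.20.

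Of 7 cyclin-dependent kinase inhibitor genes, also chosen after their values were seen, 3 rose, in libraries in which 23 of 26 cell cycle genes, 12 of 15 macrophage and monocyte, 5 of 6 neutrophil and 6 of 7 antigen presenting cell markers were higher too. Cdkn1a rose by 6.82 ± 0.61 (7.87 without 0 h replicate 3), Cdkn2a by 3.78 ± 0.61 and Cdkn2b by 2.83 ± 0.21, whereas Cdkn1c fell from 174 ± 5.48 to 14.4 ± 4.0 CPM (−3.59 ± 0.19). Arg1, an arginase gene chosen in the same way, rose from 0.616 ± 0.566 to 223 ± 44.8 CPM (log2 change 8.48, and 9.35 without 0 h replicate 1). The opioid precursor gene Penk, also chosen after its values were seen, fell from 565 ± 105 to 34.1 ± 15.8 CPM.

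In the 3 patterns weighed next, the tests of a single 0 h library, of residual fiber cells and of the share of counts were chosen after the results were seen, and the others before. The rule for fiber genes was also reworded once after its value was seen, with the same outcome. In 72 h replicate 3, keratins of surface epithelium stood far above the other two 72 h libraries. Of 12 tested surface epithelium genes outside the fixed list, none held by another list and 2 at 10 CPM or more at 0 h, 75% (9 genes) were at least 4-fold above both in that library, against 2.04% of all tested genes. The most abundant fixed markers there were Krt15 at 2157 CPM and Krt5 at 1107 CPM. A mislabelled library is argued against, because 94.7% of genes called between the other 5 libraries lay on the 72 h side there. A candidate explanation, as a hypothesis, is that this pool carried cells of the cornea or conjunctiva; a biological difference between pools was not tested.

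Photoreceptor genes were lower at 72 h, with log2 changes from −3.96 to −1.81 over the 12 fixed markers. One 0 h library with more retinal reads is argued against as the whole cause, since the median change was −2.52 without 0 h replicate 1. Retinal reads carried over at dissection are a candidate explanation, as a hypothesis. Of 27 other retinal genes, none held by another list and 7 still at 10 CPM or more at 72 h, 77.8% were at least 1.5-fold higher in 0 h replicate 1 than in 0 h replicate 2 (9.99% of all genes), short of the 80% set beforehand. Carried-over reads and lower expression in lens cells therefore cannot be told apart. Between those libraries the log2 ratio was 1.35 ± 0.14 over the 12 fixed markers (SD over genes). It was 1.02 ± 0.49 over the 27 other retinal genes and 0.01 ± 0.58 over all 15407 tested genes.

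Most crystallin, fiber and epithelial genes of the lens were lower at 72 h (14 of 15, 16 of 17 and 12 of 15 called). Fewer residual fiber cells may lower the fiber part, but the epithelial identity genes fell too, with a median of −1.10, which such a loss does not predict. A shift in the share of crystallin and mitochondrial counts is argued against as the whole cause for those genes, because the share of counts left to other genes was 79.9% ± 0.465 at 0 h and 78.0% ± 4.14 at 72 h, a log2 ratio no lower than −0.13 in any of the 9 pairs of libraries. For the fiber and crystallin genes, the SD of the log2 changes over 30 called genes was 2.53, where a loss of cells that alone express them predicts one factor. Loss of fiber cells and lower expression per cell cannot be told apart there, because epithelial cells also express some of these genes to unknown degrees. Of the epithelial identity genes 3 were not called, Pax6 among them. Markers of macrophages and neutrophils were higher in the same libraries. Whether a lower share of lens cells lowered the epithelial genes was not tested.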
